A study of Homo sapiens with 12 samples.

How the data were processed

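RNA-seq was measured in 12 libraries of human triple-negative breast cancer cells, tumour cells that lack the oestrogen, progesterone and HER2 receptors used for therapy. The lines were HCC38, grown in RPMI-1640, and MDA-MB-231, grown in low-glucose DMEM, so line and medium cannot be told apart. Each line was either untreated or given interferon-β, a type I interferon that signals through the IFNAR1 and IFNAR2 receptor, at 400 IU/mL for 48 h. The 4 groups held 3 libraries each, which the labels call biological replicates without saying whether they were separate cultures. The p-values therefore measure the spread between these libraries, part of which may be technical. Total RNA was extracted with an RNeasy kit and the libraries were made with the strand-preserving NEBNext Ultra II Directional kit, per the labels.

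For each library the authors deposited a table of read counts per gene and a table of FPKM values, fragments per kilobase of transcript at a common depth. The submitters' processing notes name fastp 0.23.2, HTSeq 2.0.2, Cufflinks 2.2.1 and the genome build GRCh38.p13. The deposited count of a gene is a whole number of reads that was not normalized, and the deposited FPKM are estimates normalized for length and depth. The aligner, the HTSeq settings for strand and overlapping genes, and the annotation release are not given in the sources used here. A gene that overlaps another or has near-identical copies can therefore lose counts that its FPKM keep, and such genes are reported as uncertain. Each count table listed 61552 genes, of which 20495 had no symbol. The FPKM tables gave a value for 61537 of these gene identifiers, and 22 FPKM entries were not marked as complete. Coordinates are those of the deposited FPKM tables on GRCh38, counted from 1. Gene and transcript lengths, used only for one check of the closing section, came from GENCODE release 29 on GRCh38.

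Total counts per library ran from 26660038 to 43588773. The smallest replicate-to-replicate chi-square statistic per degree of freedom was 4.25, so no libraries agreed within sampling noise and all 12 were kept. In the MDA-MB-231 line the replicate numbers of the titles and the numbers in the deposited names differed. The untreated replicates 1, 2 and 3 carry the numbers 1, 2 and 4 there, and the interferon-β replicates 1, 2 and 3 carry 1, 4 and 5. Numbers 1 and 2 and numbers 4 and 5 formed 2 parts of that line, since the chi-square statistic per degree of freedom was 45.6 to 66.1 between untreated or treated libraries of different parts and 4.25 to 14.7 otherwise. Counts of called genes are therefore also given with a term for the parts and within each part, and gene lists with the term where it changes their call. These fits were chosen after seeing the data.

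The main test was the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the deposited counts. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18121 genes. Libraries were scaled by TMM (factors 0.947 to 1.03). All 12 were fitted together with 1 coefficient per group, so each p holds both lines' spread. The 5 comparisons were interferon-β against untreated in each line, the difference between those responses (MDA-MB-231 minus HCC38), and MDA-MB-231 against HCC38 without and with interferon-β. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p of a gene below is from this test unless another tool is named. Log2 fold changes (edgeR prior count 0.125) have an approximate SE that can fall short of counting error at few counts. Levels are counts scaled to a common library size (CPM), mean ± SD of 3 libraries.

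Gene lists numbering 31, with 857 entries, were fixed together with the groups, the tests and the alternatives before the data were examined. They cover interferon-stimulated antiviral genes, a 7-gene interferon signature tied to resistance to DNA damage, interferon receptors and signalling, nucleic acid sensing, MHC class I and class II antigen presentation, immune ligands, chemokines and cytokines, and NF-κB targets. Others cover the ATR-CHK1 replication stress pathway, homologous recombination and the Fanconi pathway, other DNA repair, Schlafen genes with SAMHD1, G1/S and G2/M genes, p53 targets, cell death genes and APOBEC3 enzymes. The rest cover the integrated stress and unfolded protein responses, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, histones, mesenchymal, luminal and basal markers, leukocyte markers, fibroblast and endothelial markers, and reference genes. Each list was tested against the other genes with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and adjusted over the lists. Adjusted p-values of lists are from this test. It was repeated with an estimated correlation and beside limma's fry, which tests whether a list moves one way on balance. Members were also adjusted over the list alone.

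The genes named in the text followed a fixed rule. It allowed 20 genes in any case (among them IRF3, IFNAR1, IFNAR2, STAT2, IRF9, IRF1, IRF7, CGAS, STING1, ATR, CHEK1, BRCA1, SLFN11, CD274, TNFSF10, CDKN1A, APOBEC3B and MKI67). It added the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 1 CPM and groups that did not overlap (for the difference between the lines, without the last condition). It added up to 4 members of each list by smallest p, or all members of a list of up to 7. A gene named for 1 line could be named for the other. Some genes that the rule takes are not reported here. A gene with 0 counts in a whole group is given a bound from a floor of 3 counts over that group. With 1 to 3 counts it is given as a ratio with a 95% interval. Intervals and floors cover counting error only.

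The method was first tested on simulated counts with 200 changed genes. Of the 67 changed 2-fold it recovered 85.1% for HCC38 (16 false calls, 17724 genes tested), 80.6% for MDA-MB-231 (11 false calls, 17724 genes) and 59.7% for the difference between the responses (5 false calls, 17715 genes). At a 4-fold change it recovered 100%, 93.9% and 86.4%. With 2 simulated parts of the MDA-MB-231 libraries (17727 genes) it recovered 59.7% for HCC38 and 56.7% for MDA-MB-231 at 2-fold, and 85.1% and 73.1% with a term for the parts.

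Alternatives were median-of-ratios size factors and library totals in place of TMM, a minimum of 1 CPM in 3 libraries or no filter, DESeq2 1.42.0, limma-voom, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean FPKM of at least 1, or of all genes. Others were a test against a 1.5-fold change, a fit of the 6 libraries compared alone, replicate numbers as a block, and each library left out in turn. Fold changes of FPKM are on the log2(FPKM + pseudocount) scale, which understates changes of low genes. Figures and resampling used Python 3.11.15 and matplotlib 3.10.9. A search of promoters for interferon response elements was planned and not run, since it needs a genome sequence.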

Results

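Gene expression was measured by RNA-seq in HCC38 and MDA-MB-231, human triple-negative breast cancer lines, without treatment and after 48 h of interferon-β at 400 IU/mL, with 3 libraries in each of the 4 groups. The title of the series names the transcription factor IRF3, replication stress signalling and sensitivity to genotoxic agents. The comparisons thus ask how type I interferon changed expression in each line, whether the lines differed in that response, and how they differed with and without it. Total counts of replicates 1, 2 and 3 were 31846858, 37116456 and 29416294 in untreated HCC38 and 26660038, 31492542 and 26743761 in treated HCC38. They were 28757721, 34408108 and 43588773 in untreated MDA-MB-231 and 34122062, 28865539 and 39137471 in treated MDA-MB-231. Between 21599 and 24247 genes were detected per library. The 10 genes with most counts took 3.39% to 5.50% of the counts of a library. The share of mitochondrially encoded transcripts was 2.17% to 2.68% in untreated and 1.35% to 1.94% in treated HCC38, and 2.07% to 3.39% and 1.07% to 2.53% in MDA-MB-231.

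Of the key genes, OAS1 (ENSG00000089127) lies on chromosome 12 at 112905856 to 112933219 of GRCh38 and MX1 (ENSG00000157601) on chromosome 21 at 41420020 to 41470071. ISG15 (ENSG00000187608) lies on chromosome 1 at 1001138 to 1014540, HLA-B (ENSG00000234745) on chromosome 6 at 31353872 to 31367067 and IRF3 (ENSG00000126456) on chromosome 19 at 49659569 to 49665875. RPLP0 (ENSG00000089157) lies on chromosome 12 at 120196699 to 120201235, SLFN11 (ENSG00000172716) on chromosome 17 at 35350305 to 35373701 and NT5E (ENSG00000135318) on chromosome 6 at 85449584 to 85495791.

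In HCC38, interferon-β raised genes of the antiviral state, 13 of 21 of MHC class I presentation and 7 of 21 of nucleic acid sensing, and lowered 29 of 42 of ribosomal proteins. The ribosomal list was not called with an estimated correlation once the parts of the MDA-MB-231 libraries had a term (adjusted p = 0.0624). IFI27, a mitochondrial interferon-induced protein, rose from 6.33 ± 0.0704 to 196 ± 13.1 CPM (SD, n = 3), a log2 fold change of 4.95 ± 0.09 (SE). MX1, a GTPase that blocks viral replication, rose from 256 ± 11.5 to 889 ± 50.5 CPM, and OAS1, which makes the oligoadenylates that activate RNase L, rose from 55.1 ± 0.155 to 228 ± 3.04 CPM. RPLP0, a protein of the ribosomal stalk, fell from 1336 ± 53.5 to 858 ± 47.0 CPM. By edgeR, 659 of 18121 genes were called, 433 higher and 226 lower, and 2941 had an unadjusted p under 0.05. At least a 2-fold change was estimated for 136 of the higher and 37 of the lower genes, and a 4-fold change for 35 and 9. The count was lower without untreated replicate 1 (340), 2 (371) or 3 (341) and without treated replicate 1 (342) or 3 (378). It was 402 on log2(FPKM + 1), 88 against a 1.5-fold change, 1131 with no filter, 1136 in DESeq2, 1959 in a fit of its 6 libraries and 1913 with a term for the parts of the MDA-MB-231 libraries.

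All 60 tested antiviral genes had a higher estimate in treated HCC38. The test called 57 of them higher over all genes and 60 adjusted over the list alone, with a median log2 fold change of 1.41 (camera, adjusted p = 9.08e-83). Besides OAS1 (2.05 ± 0.08, adjusted p = 1.85e-09) and MX1 (1.80 ± 0.09, adjusted p = 2.37e-08), they included ISG15, a ubiquitin-like modifier, which rose from 77.4 ± 8.74 to 253 ± 36.3 CPM. IFIT1, which binds viral RNA, rose by 2.24 ± 0.38 (adjusted p = 0.00365) and IFIT3 by 2.2 ± 0.25. All 7 genes of the interferon signature tied to resistance to DNA damage rose, also adjusted over the list alone, with a median of 1.80 (camera, adjusted p = 2.37e-17). Among the largest rises outside these names were those of CMPK2, a mitochondrial nucleotide kinase, from 2.98 ± 0.417 to 28.5 ± 1.66 CPM (3.26 ± 0.16) and of RSAD2, the antiviral enzyme viperin (2.94 ± 0.21). NT5E, the ectonucleotidase CD73 that makes adenosine, rose from 4.42 ± 0.371 to 33.4 ± 4.23 CPM (2.92 ± 0.12, adjusted p = 4.53e-09). Among the largest falls were LGR4, a receptor for R-spondins, from 25.7 ± 1.00 to 9.32 ± 0.764 CPM (-1.46 ± 0.14) and the protease gene ADAMTS16 (-1.41 ± 0.20). ACTA2, smooth muscle actin, fell from 60 ± 3.00 to 26.8 ± 2.96 CPM (-1.16 ± 0.21, adjusted p = 0.0063), a call lost without treated replicate 1 (adjusted p = 0.0569).

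Among genes of interferon signalling, 2 of 22 rose in HCC38 (3 adjusted over the list alone), including STAT2 at 0.69 ± 0.10 (adjusted p = 0.0014). The list median was 0.05, or 0.06 with genes at 0 counts at their bound (camera, adjusted p = 0.0151), and this call was lost (adjusted p = 0.125 with an estimated correlation). The receptor genes IFNAR1 (107 ± 6.09 and 114 ± 5.65 CPM) and IFNAR2 (9.92 ± 0.486 and 9.90 ± 0.715 CPM) did not pass the test. IRF3, a transcription factor activated downstream of cGAS and STING, was at 37.7 ± 4.47 and 34.7 ± 3.67 CPM (-0.12 ± 0.13, adjusted p = 0.721). IRF1 was at 61.2 ± 1.93 and 78.8 ± 2.76 CPM (no overlap, adjusted p = 0.328). Its p also reflects MDA-MB-231's spread. IRF7 had 0 counts in all 6 libraries. IRF9 was at 1.90 ± 0.709 and 1.98 ± 0.167 CPM (adjusted p = 0.984), few counts beside its deposited FPKM of 50.4 ± 2.77 and 59.6 ± 3.42, so its counts are uncertain. In nucleic acid sensing, 7 of 21 genes rose (11 adjusted over the list alone), with a median of 0.28 (camera, adjusted p = 1.16e-08). They included IFIH1, the RNA sensor MDA5 (80.3 ± 6.27 to 239 ± 23.7 CPM), and ADAR, an RNA-editing enzyme (796 ± 18.1 to 1148 ± 11.4 CPM). The DNA sensor CGAS (0.21, adjusted p = 0.135) and its partner STING1 (0.43, adjusted p = 0.0969) did not pass.

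MHC class I presentation genes rose in HCC38 for 13 of 21 members (16 adjusted over the list alone), with a median of 0.56 (camera, adjusted p = 7.17e-20). HLA-B rose from 889.5 ± 40.6 to 2063 ± 148 CPM (1.21 ± 0.11), HLA-F by 1.23 ± 0.10, the peptide transporter gene TAP1 by 0.94 ± 0.11 and the immunoproteasome subunit PSMB9 by 0.71 ± 0.11. Because the HLA genes are close paralogs, reads could be split between them. MHC class II genes rose for 2 of 13 members, also adjusted over the list alone, among them the invariant chain CD74 (2.11 ± 0.28), with a list median of 0.40 (camera, adjusted p = 0.0454). That call was lost without untreated replicate 2 (adjusted p = 0.0706) or 3 (0.0676) and treated replicate 1 (0.0560) or 2 (0.124), and with the term for the parts (0.0578). It was also lost (adjusted p = 0.475 with an estimated correlation). Immune ligands rose for 6 of 19 members (9 adjusted over the list alone; median 0.50; camera, adjusted p = 1.18e-08), including CEACAM1 (1.26 ± 0.17). CD274, the ligand PD-L1, was at 21.2 ± 1.73 and 41.8 ± 2.95 CPM and did not pass (no overlap, 0.98 ± 0.29, adjusted p = 0.0861). Its p also reflects MDA-MB-231's spread. Chemokines and cytokines rose for 4 of 12 members (7 adjusted over the list alone, median 0.47, camera, adjusted p = 6.86e-06). IL6, a member of the NF-κB list and not of this one, rose from 2.37 ± 0.167 to 6.62 ± 1.15 CPM. Of the NF-κB targets, 2 of 23 rose (5 higher and 1 lower adjusted over the list alone), BIRC3 and IL6 among them, with a median of 0.28, or 0.29 with genes at 0 counts at their bound. That list's call (camera, adjusted p = 0.00368) was lost (adjusted p = 0.503 with an estimated correlation).

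Cell death genes rose in HCC38 for 8 of 35 members (12 adjusted over the list alone), with a median of 0.09 (camera, adjusted p = 8.66e-05). PMAIP1, the proapoptotic protein NOXA, rose from 84.1 ± 4.28 to 158 ± 9.59 CPM (0.90 ± 0.10), and BIRC3, an inhibitor of apoptosis, by 1.11 ± 0.20. The death ligand TNFSF10, TRAIL, rose from 8.84 ± 0.924 to 18.6 ± 1.53 CPM (adjusted p = 0.00719), a call lost without untreated replicate 1 (adjusted p = 0.0503). For DNA replication stress, 0 of 36 genes of the ATR-CHK1 pathway passed in edgeR over all genes or adjusted over the list alone, 4 being higher and 2 lower at an unadjusted p under 0.05. DESeq2 called 2 higher and limma-voom 0, and the list median was 0.06 (camera, adjusted p = 0.176). CHEK1, the CHK1 kinase, was at 37.3 ± 1.53 and 43.0 ± 2.2 CPM (0.21 ± 0.08, adjusted p = 0.225) and ATR at 102 ± 8.82 and 105 ± 5.51 CPM. The genes of homologous recombination and the Fanconi pathway had a median of 0.16 (camera, adjusted p = 0.00208). This call was lost (adjusted p = 0.575 with an estimated correlation). Of its 38 members 0 passed in edgeR over all genes, with 7 higher at an unadjusted p under 0.05, 1 higher in DESeq2 and 0 in limma-voom. With the term for the parts of the MDA-MB-231 libraries, 10 of these genes rose in HCC38 (camera, adjusted p = 4.24e-05; adjusted p = 0.162 with an estimated correlation), and 5 of the ATR-CHK1 genes rose and 2 fell (camera, adjusted p = 0.0437; adjusted p = 0.405 with an estimated correlation). BRCA1 was at 30.6 ± 3.82 and 34.2 ± 1.32 CPM (adjusted p = 0.699). Other DNA repair genes had a median of 0.01 (adjusted p = 0.625).

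Of the Schlafen and SAMHD1 list, 2 of 11 genes rose in HCC38 (3 adjusted over the list alone), with a median of 0.16, or 0.18 with genes at 0 counts at their bound (camera, adjusted p = 0.00722). SAMHD1, which hydrolyses deoxynucleotides, rose from 214 ± 16.9 to 434 ± 8.82 CPM (1.02 ± 0.07). SLFN11, a DNA-damage sensitizer, was at 113 ± 6.19 and 126 ± 0.920 CPM (0.16, adjusted p = 0.441). The G1/S genes had a median of 0.14 with 1 of 50 higher, also adjusted over the list alone, which was CCND1, cyclin D1 (417 ± 1.48 to 573 ± 17.4 CPM). That list was called by camera (adjusted p = 0.000305), a call lost (adjusted p = 0.575 with an estimated correlation). Fitted with the term for the parts, 7 rose and 2 fell (adjusted p = 0.0359 with an estimated correlation). The G2/M genes had a median of 0.05 (camera, adjusted p = 0.391). Among p53 targets (median -0.00; camera, adjusted p = 0.798) 1 of 28 rose and 1 fell (2 and 1 adjusted over the list alone). CDKN1A, the inhibitor p21, was at 10.8 ± 1.91 and 15.6 ± 1.95 CPM (adjusted p = 0.0572), and passed without untreated replicate 1 (0.69, adjusted p = 0.0324).

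Ribosomal protein genes fell in HCC38 for 29 of 42 members (40 adjusted over the list alone), with a median of -0.43 (camera, adjusted p = 2.51e-27). The median was -0.42 with median-of-ratios size factors and -0.44 with library totals, so the direction held under each scaling. RPL7 fell from 1394 ± 44.8 to 989 ± 35.4 CPM. These genes have many processed pseudogenes, so reads could be shared. Mitochondrially encoded genes, of which 1 of 13 fell (also adjusted over the list alone), had a median of -0.64 (camera, adjusted p = 0.00014; adjusted p = 0.479 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell for 3 of 36 members (6 adjusted over the list alone), with a median of -0.13 (camera, adjusted p = 8.66e-05; adjusted p = 0.264 with an estimated correlation). Histone genes rose for 3 of 16 members (5 adjusted over the list alone), with a median of 0.37 (camera, adjusted p = 6.61e-06), such as the linker histone H1-2 (590.3 ± 13 to 934 ± 71.2 CPM) and the core histone H4C8 (0.85 ± 0.11). Once the parts had a term, the ribosomal protein (adjusted p = 0.0624), histone (0.0594), immune ligand (0.0650), cell death (0.103) and Schlafen and SAMHD1 (0.0849) lists were not called with an estimated correlation.

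Mesenchymal genes went both ways in HCC38, with 6 of 31 higher and 2 lower (9 and 4 adjusted over the list alone) and a median of 0.02 (camera, adjusted p = 0.222). AXL, a receptor kinase, rose from 169.5 ± 7.28 to 299 ± 14.0 CPM. TGFBI, an extracellular matrix protein, fell from 1656 ± 93.7 to 1123 ± 19.7 CPM. Basal markers rose for 1 and fell for 1 of 22 members (5 and 2 adjusted over the list alone), with a median of 0.20 (camera, adjusted p = 0.0241; adjusted p = 0.0734 with an estimated correlation, or 0.0481 with the term for the parts). This call was lost without untreated replicate 2 (adjusted p = 0.0787) or treated replicate 2 (0.0544). Luminal markers had a median of 0.00 (camera, adjusted p = 0.959). Markers of other cell types were not called as lists: leukocyte markers had a median of 0.12 (adjusted p = 0.314, 1 of 9 higher) and fibroblast and endothelial markers of -0.29, or -0.32 with genes at 0 counts at their bound (adjusted p = 0.332, 2 of 13 lower). The lower ones were the matrix genes COL3A1 (-0.77 ± 0.14) and POSTN (-0.55 ± 0.10). The stress response list (median -0.08, adjusted p = 0.475), cholesterol synthesis (-0.06, adjusted p = 0.332), glycolysis and hypoxia (-0.07, adjusted p = 0.332) and reference genes (-0.01, adjusted p = 0.584) were not called. APOBEC3 genes had a median of 0.55, or 0.41 with genes at 0 counts at their bound (adjusted p = 0.0558), and passed without untreated replicate 1 (adjusted p = 0.0197) and with the term for the parts (0.0156; adjusted p = 0.0849 with an estimated correlation).

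**Figure D1:**
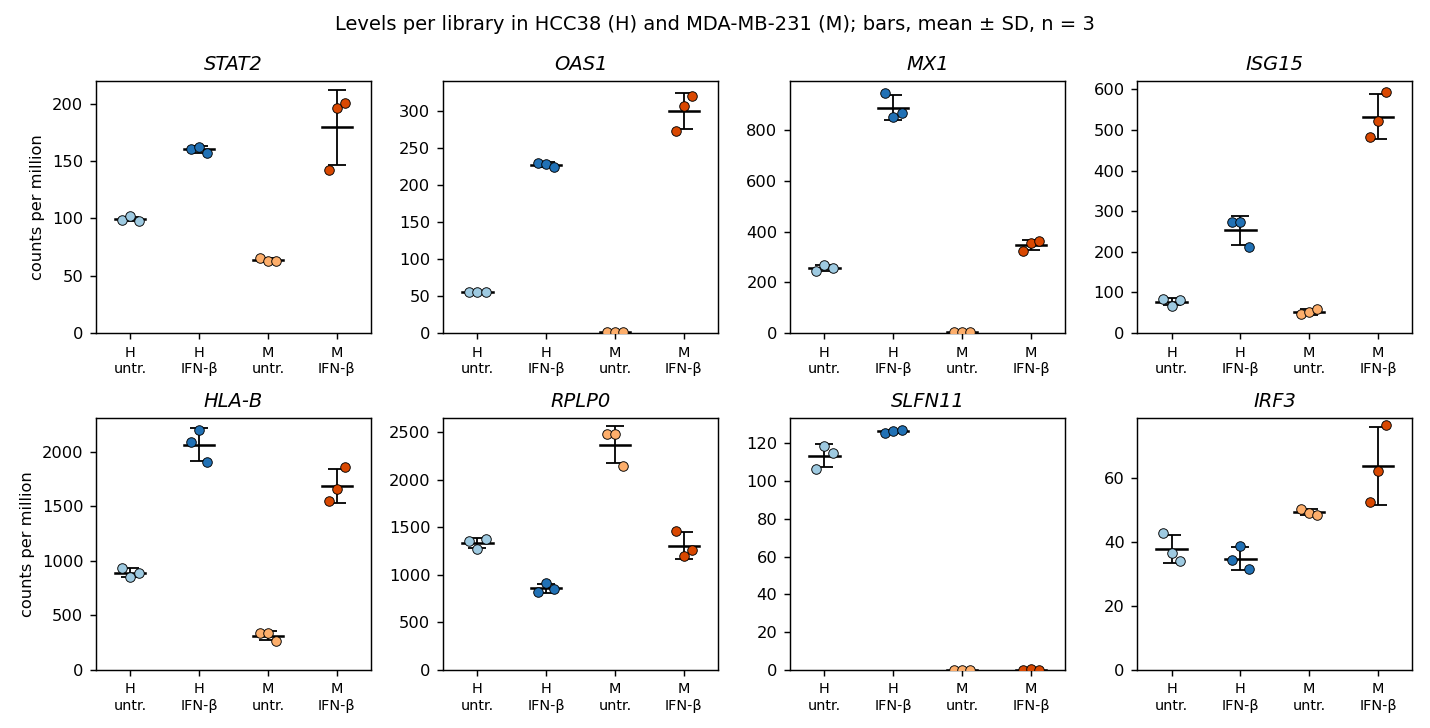
Level in CPM (vertical axes, starting at 0) of STAT2, OAS1, MX1, ISG15, HLA-B, RPLP0, SLFN11 and IRF3 in untreated and interferon-β-treated HCC38 and MDA-MB-231. Points are single libraries and bars are means ± SD of 3 libraries; OAS1 goes from 1.10 to 301 CPM in MDA-MB-231 and from 55.1 to 228 CPM in HCC38, while SLFN11 has means of 0.0461 and 0.0919 CPM in MDA-MB-231.

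In MDA-MB-231 most antiviral genes started lower and most rose further, MHC class II and chemokine genes rose with them, and genes of ribosomal proteins fell. Neither the lower start nor the ribosomal protein list (adjusted p = 0.116) was called with an estimated correlation. Nor was MHC class II once the parts of the libraries had a term (adjusted p = 0.0972). OAS1 rose from 1.10 ± 0.151 to 301 ± 24.2 CPM (n = 3), a log2 fold change of 8.07 ± 0.11 (SE), and IFI27 from 0.397 ± 0.0630 to 256 ± 16.1 CPM (9.35 ± 0.13). MX1 rose from 2.98 ± 0.426 to 346 ± 20.0 CPM, and IFITM1, a membrane protein that blocks viral entry, from 1.28 ± 0.337 to 251 ± 8.85 CPM. PRKDC, the catalytic subunit of DNA-PK, fell from 923 ± 245 to 475 ± 36.4 CPM (-0.96 ± 0.14, adjusted p = 0.000402). By edgeR, 2272 of 18121 genes were called, 1170 higher and 1102 lower (51.5% higher), with 4770 at an unadjusted p under 0.05. With library totals in place of TMM, 71.3% of the called genes were higher. At least a 2-fold change was estimated for 492 of the higher and 72 of the lower genes, and a 4-fold change for 202 and 5. The count was 1371 without treated replicate 2 and 1168 without treated replicate 3, 1181 on log2(FPKM + 1), 1035 in a fit of its 6 libraries and 275 against a 1.5-fold change.

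The libraries of this line fell into 2 parts by the numbers in their deposited names, untreated replicates 1 and 2 with treated replicate 1, and untreated replicate 3 with treated replicates 2 and 3. In a principal component analysis of the line, the first component held 45.8% of the variance and the second, which separated the parts, 26.8%. With a term for the parts, 4095 genes were called, 2102 higher and 1993 lower, of which 2261 were shared with the 2272 in direction. Within the first part alone 1176 genes were called (712 higher, 464 lower), and within the second 3710 (1805 higher, 1905 lower). Each of these fits leaves 1 group with a single library, which is assumed to vary like the others. The parts' responses differed for 11 genes. Median log2 fold changes of lists within the first and second part were 2.40 and 2.53 for antiviral genes, 1.16 and 3.08 for MHC class II, 0.20 and 0.67 for immune ligands, 0.06 and 0.28 for cell death genes, -0.26 and -0.51 for ribosomal protein genes, 0.01 and -0.26 for the stress responses and 0.58 and -0.02 for the Schlafen and SAMHD1 list. Lists whose call changed with the term are given with both values.

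Of the 60 antiviral genes 59 rose, also adjusted over the list alone, with a median of 2.55, or 2.57 with genes at 0 counts at their bound (camera, adjusted p = 3.44e-86). IFI44L rose from 1.26 ± 0.566 to 341 ± 47.7 CPM (8.04 ± 0.23) and ISG15 from 51.9 ± 6.68 to 533 ± 55.7 CPM (3.36 ± 0.14, adjusted p = 3.33e-10). HSH2D, an adaptor protein outside the antiviral list, rose from 0.0936 ± 0.0473 to 17.7 ± 0.934 CPM. TRIM22, a ubiquitin ligase with antiviral activity, rose by 7.78 ± 0.29, or 8.43 without untreated replicate 1. IFIT1 rose by 3.27 ± 0.39, or 4.17 without untreated replicate 3. Each of the 7 signature genes rose, also adjusted over the list alone, with a median of 3.27 (camera, adjusted p = 3.02e-18). CMPK2, which rose in HCC38, had 0 counts in untreated and 1 count in treated MDA-MB-231. The collagenase gene MMP13 rose from 0.0361 ± 0.0364 to 3.68 ± 0.804 CPM (6.43 ± 0.38), or by 7.51 without untreated replicate 3, which held 3 of the 4 untreated counts.

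Interferon signalling genes rose in MDA-MB-231 for 7 of 22 members (11 higher and 1 lower adjusted over the list alone), with a median of 0.23 (camera, adjusted p = 4.45e-05). STAT2 rose from 63.6 ± 1.49 to 179 ± 32.7 CPM. IRF7, a transcription factor that amplifies interferon production, rose from 6.35 ± 1.34 to 88.8 ± 9.23 CPM (3.82 ± 0.17, adjusted p = 1.11e-07). IRF9 rose from 0.582 ± 0.23 to 3.57 ± 1.96 CPM (adjusted p = 0.00215), though not in the first part alone (1.45, adjusted p = 0.0773), and from 10.7 ± 1.51 to 81.7 ± 2.34 in the deposited FPKM (limma, adjusted p = 7.69e-09). IRF3 was at 49.2 ± 0.992 and 63.6 ± 12.1 CPM (0.37 ± 0.13, adjusted p = 0.0719), and passed without treated replicate 1 (0.49, adjusted p = 0.00864). IFNAR1 was at 84.0 ± 2.69 and 74.4 ± 7.55 CPM (adjusted p = 0.19), and was called lower without treated replicate 1 (-0.27, adjusted p = 0.0310). IFNAR2 (0.14, adjusted p = 0.528) and IRF1 (0.22, adjusted p = 0.476) did not pass. In nucleic acid sensing 9 of 21 genes rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.27 (camera, adjusted p = 1.22e-05). IFIH1 rose from 26.5 ± 5.17 to 197 ± 2.11 CPM and STING1 from 41.9 ± 7.10 to 77.8 ± 10.9 CPM (0.90 ± 0.13, adjusted p = 0.000385). CGAS was at 53.5 ± 1.26 and 52.1 ± 2.24 CPM (adjusted p = 0.809).

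MHC class I genes rose for 15 of 21 members and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.81 (camera, adjusted p = 8.28e-18). HLA-B rose from 311 ± 42.9 to 1684 ± 158 CPM, TAP1 from 34.0 ± 6.07 to 172 ± 12.3 CPM and PSMB9 from 4.65 ± 0.670 to 33.4 ± 5.53 CPM. MHC class II genes rose for 9 of 13 members (10 adjusted over the list alone), with a median of 2.17, or 1.93 with genes at 0 counts at their bound (camera, adjusted p = 4.85e-08). CD74 rose by 2.17 ± 0.29 and HLA-DPA1 from 0.130 ± 0.0518 to 1.17 ± 0.411 CPM. Chemokines and cytokines rose for 8 of 12 members (11 adjusted over the list alone), with a median of 1.52, or 1.39 with genes at 0 counts at their bound (camera, adjusted p = 5.75e-08). IL6 rose from 7.31 ± 0.156 to 21.2 ± 3.71 CPM and CXCL16, a chemokine for T cells, by 1.73 ± 0.22. Immune ligands rose for 9 of 19 members (10 adjusted over the list alone; median 0.45; camera, adjusted p = 1.98e-05), including PDCD1LG2, the ligand PD-L2 (1.63 ± 0.25). CD274 was at 13.2 ± 5.04 and 18.1 ± 8.16 CPM (adjusted p = 0.367), and passed without treated replicate 1 (0.77, adjusted p = 0.0158). NF-κB targets rose for 4 of 23 members, also adjusted over the list alone, among them IL1B (5.22 ± 0.880 to 14.0 ± 2.36 CPM). Their list, with a median of 0.24, or 0.22 with genes at 0 counts at their bound, had a camera adjusted p of 0.0501. It passed without untreated replicate 1 (0.00992) or 2 (0.0317) or treated replicate 2 (0.00196) or 3 (0.00832). When the parts had a term, 13 rose (camera, adjusted p = 2.17e-05; adjusted p = 0.0972 with an estimated correlation). In that fit MHC class I (adjusted p = 0.0567), class II (0.0972) and immune ligands (0.127) were not called with an estimated correlation.

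Cell death genes rose in MDA-MB-231 for 10 of 35 members, also adjusted over the list alone, with a median of 0.14 (camera, adjusted p = 0.000833; adjusted p = 0.0822 with an estimated correlation). APOL1, a lipoprotein that forms ion channels, rose from 5.53 ± 1.44 to 28.6 ± 5.22 CPM (2.36 ± 0.18), and the death receptor FAS by 1.44 ± 0.21. TNFSF10 had 0 counts in the untreated libraries and 0.817 ± 0.333 CPM after treatment, which is at least 27.9-fold higher against a floor of 3 counts over the group (adjusted p = 5.11e-05). In the ATR-CHK1 pathway 1 of 36 genes rose and 2 fell (0 and 1 adjusted over the list alone), with a median of -0.07 (camera, adjusted p = 0.16). The list was called lower without untreated replicate 1 (adjusted p = 0.0310) or 2 (0.00989) or treated replicate 2 (0.0281). With the term for the parts 1 rose and 11 fell, with a median of -0.18 (camera, adjusted p = 0.000335; adjusted p = 0.134 with an estimated correlation). CHEK1 was at 84.4 ± 7.72 and 75.9 ± 3.21 CPM (-0.15 ± 0.08, adjusted p = 0.246) and ATR at 85.3 ± 15.7 and 71.1 ± 5.63 CPM (-0.26, adjusted p = 0.155).

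The homologous recombination and Fanconi genes had 2 members higher and 1 lower of 38 (1 and 0 adjusted over the list alone), with a median of -0.02 (camera, adjusted p = 0.952; 0.0161 with the term for the parts, and there adjusted p = 0.326 with an estimated correlation). BRCA1 was at 113 ± 25.8 and 114 ± 22.6 CPM. Of 45 other DNA repair genes 10 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.06, or -0.07 with genes at 0 counts at their bound (camera, adjusted p = 0.021; adjusted p = 0.164 with an estimated correlation). Besides PRKDC, DDB1, a subunit of the complex that recognises ultraviolet lesions, fell from 521 ± 17.9 to 390.1 ± 34.6 CPM. The list was not called without untreated replicate 3 (adjusted p = 0.104) or treated replicate 1 (0.0762), and with the term for the parts 14 fell and 1 rose (camera, adjusted p = 0.00523; adjusted p = 0.0972 with an estimated correlation). In the Schlafen and SAMHD1 list 3 of 11 genes rose, also adjusted over the list alone, SAMHD1 from 134 ± 5.47 to 685 ± 8.97 CPM (2.36 ± 0.08, adjusted p = 1.91e-11). Its median was 0.01 (camera, adjusted p = 0.0431; adjusted p = 0.116 with an estimated correlation), and the call was lost without treated replicate 1 (adjusted p = 0.0991) or 2 (0.0539). SLFN11 was at 0.0461 ± 0.0232 and 0.0919 ± 0.0587 CPM (adjusted p = 0.545).

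Of 50 genes of G1/S and DNA replication 5 fell in MDA-MB-231, also adjusted over the list alone, with a median of -0.13 (camera, adjusted p = 0.000893; adjusted p = 0.589 with an estimated correlation). The helicase subunit MCM6 fell from 146 ± 15.5 to 94.5 ± 4.40 CPM (-0.63 ± 0.08, adjusted p = 0.000209). The list was not called without untreated replicate 3 (adjusted p = 0.137) or treated replicate 1 (0.404). With the term for the parts 28 fell, with a median of -0.23 (camera, adjusted p = 3.72e-11; adjusted p = 0.00932 with an estimated correlation). Of the 37 G2/M genes 0 passed in edgeR, with 1 higher at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. The list median was 0.06 (camera, adjusted p = 0.684), and the list was called higher without untreated replicate 3 (adjusted p = 3.00e-06) or treated replicate 1 (0.0248). Once the parts had a term, 11 G2/M genes fell, with a median of -0.14 (camera, adjusted p = 0.000155; adjusted p = 0.332 with an estimated correlation). MKI67, a proliferation marker, was at 975 ± 471 and 829 ± 168 CPM (-0.23, adjusted p = 0.584). Of 28 p53 targets 2 rose and 2 fell, also adjusted over the list alone (median 0.02; camera, adjusted p = 0.952). CDKN1A rose from 42.0 ± 4.93 to 65.1 ± 7.43 CPM (0.63 ± 0.13, adjusted p = 0.00629). APOBEC3 genes had 1 of 6 higher (2 and 2 lower adjusted over the list alone; median 0.27; camera, adjusted p = 0.336).

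Ribosomal protein genes fell for 26 of 42 members (32 adjusted over the list alone), with a median of -0.38 (camera, adjusted p = 3.02e-18; adjusted p = 0.116 with an estimated correlation). The median was -0.38 with median-of-ratios size factors and -0.30 with library totals, which called 21 lower. RPLP0 fell from 2372 ± 194 to 1306 ± 139.5 CPM and RPL7 from 1311 ± 5.45 to 679.5 ± 58.2 CPM. Mitochondrially encoded genes fell for 2 of 13 members (3 adjusted over the list alone), with a median of -0.57 (camera, adjusted p = 0.00121; adjusted p = 0.494 with an estimated correlation). That list was not called without untreated replicate 3 (adjusted p = 0.0794) or treated replicate 1 (0.0819). Fitted with the term for the parts, 12 fell, with a median of -0.89 (camera, adjusted p = 9.64e-07; adjusted p = 0.221 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell for 4 of 36 members, also adjusted over the list alone, with a median of -0.09 (camera, adjusted p = 0.0501). They passed as a list without untreated replicate 1 (adjusted p = 0.00116) or treated replicate 1 (0.0236), and with the term for the parts (0.0439; adjusted p = 0.465 with an estimated correlation). Genes of the integrated stress and unfolded protein responses fell for 3 of 25 members (4 adjusted over the list alone), such as PSAT1 of serine synthesis (237 ± 40.0 to 116 ± 33.5 CPM). Their median was -0.24, or -0.22 with genes at 0 counts at their bound (camera, adjusted p = 0.000891; adjusted p = 0.424 with an estimated correlation). Glycolysis and hypoxia genes rose for 5 and fell for 2 of 29 members (5 and 4 adjusted over the list alone; median 0.13; camera, adjusted p = 0.157), and for 10 and 4 with the term for the parts (0.0256; adjusted p = 0.332 with an estimated correlation). The glucose transporter SLC2A1 rose from 722 ± 15.8 to 1178 ± 68.6 CPM.

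Luminal markers rose for 9 of 19 members and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.48, or 0.49 with genes at 0 counts at their bound (camera, adjusted p = 0.000893; adjusted p = 0.116 with an estimated correlation). EPCAM, an epithelial adhesion molecule, rose from 2.58 ± 0.481 to 4.57 ± 0.215 CPM. CDH1, E-cadherin, had 3 counts over the untreated libraries and 54 over the treated ones, a ratio of 17.7 (95% counting interval 5.76 to 88.7). The 3 counts were in untreated replicate 3. Mesenchymal genes rose for 9 of 31 members and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.21, or 0.22 with genes at 0 counts at their bound (camera, adjusted p = 0.0212; adjusted p = 0.165 with an estimated correlation). TGFBI rose from 404 ± 43.3 to 540.1 ± 12.5 CPM, while AXL fell from 1096 ± 47.6 to 829.9 ± 53.8 CPM. Histone genes rose for 3 of 16 members (5 adjusted over the list alone), H1-2 from 19.4 ± 0.937 to 41.0 ± 1.94 CPM, with a list median of 0.00, or 0.95 with 7 genes at 0 counts at their bound or left out (camera, adjusted p = 0.0571). The histone list passed without untreated replicate 3 (adjusted p = 0.0339). Basal markers (median 0.21) and reference genes (-0.02) each had an adjusted p of 0.0933, and both passed without untreated replicate 2 (0.0435 and 0.0439), as did reference genes with the term for the parts (0.0483; adjusted p = 0.326 with an estimated correlation). The cholesterol synthesis list was at 0.00 (adjusted p = 0.927), or 0.0355 without treated replicate 1. Markers of other cell types were not called as lists: leukocyte markers had a median of 0.33, or 0.24 with genes at 0 counts at their bound (adjusted p = 0.443). Fibroblast and endothelial markers had a median of 0.76, or 0.68 at the bound (adjusted p = 0.0933), and passed without treated replicate 1 (0.0487).

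**Figure D2:**
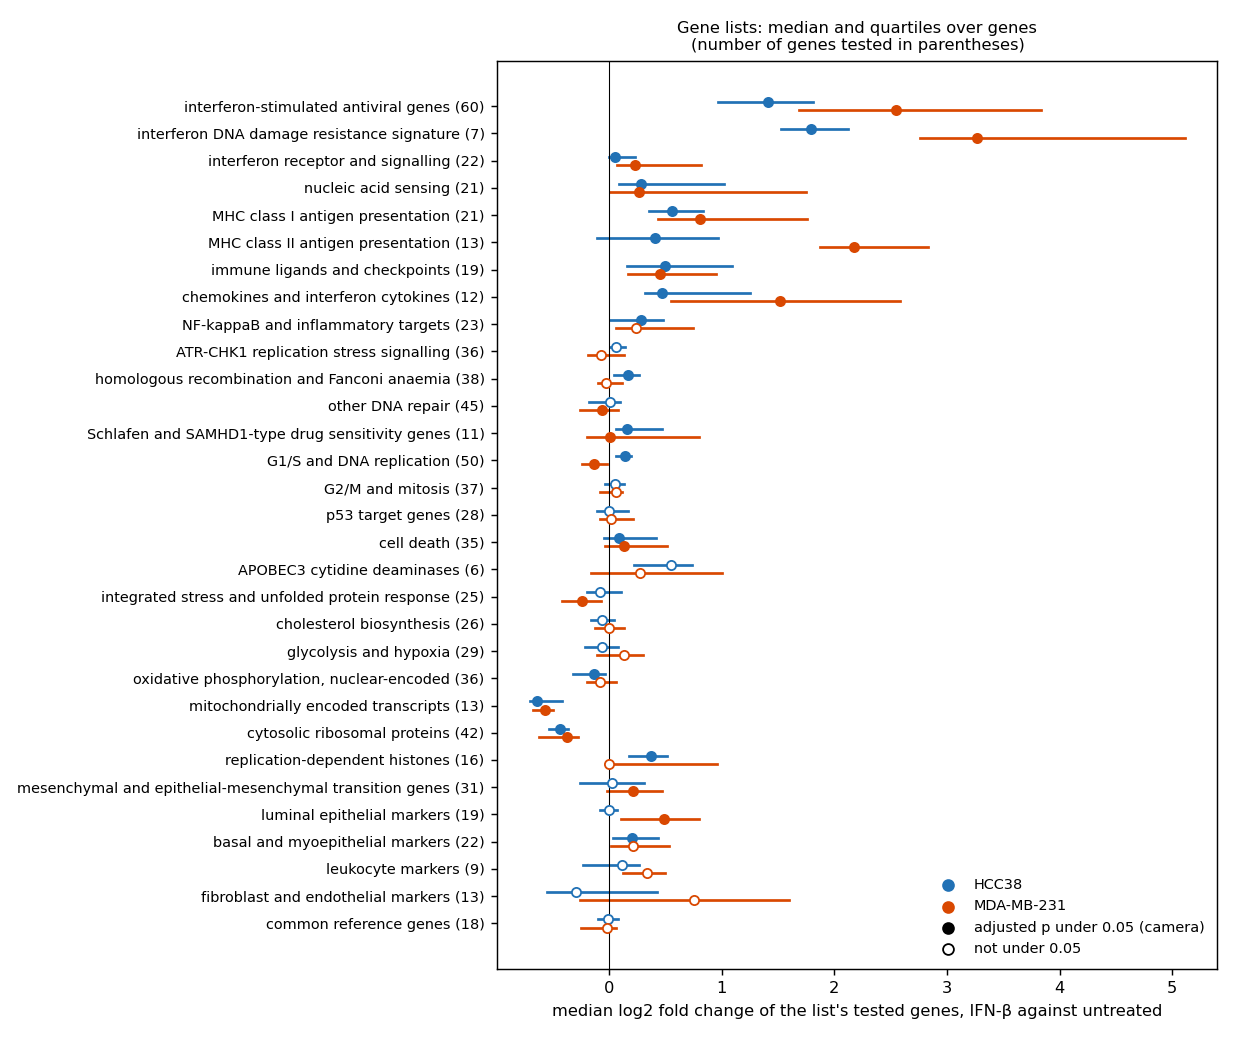
Median log2 fold change after interferon-β (horizontal axis) of the 31 gene lists in HCC38 and MDA-MB-231, with the number of tested members in parentheses. Points are medians, lines run from the lower to the upper quartile, and filled points passed camera at an adjusted p under 0.05; the antiviral list lies at 1.41 in HCC38 and 2.55 in MDA-MB-231, and the ribosomal protein list at -0.43 and -0.38.

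The response of MDA-MB-231 was compared with that of HCC38 by the difference of their log2 fold changes. The antiviral genes rose more in MDA-MB-231, where most of them had the lower untreated level. OAS1 differed by 6.02 ± 0.13 (SE, adjusted p = 1.51e-12), MX1 by 5.07 ± 0.14 and IFI44L by 5.70 ± 0.27. NT5E went the other way, at 582 ± 68.1 and 525 ± 29 CPM in MDA-MB-231 against its rise in HCC38 (-3.06 ± 0.16, adjusted p = 2.24e-08). In all, 637 of 18121 genes differed in edgeR, 361 higher and 276 lower (56.7% higher), with 3368 at an unadjusted p under 0.05. With library totals 74.0% were higher. At least a 2-fold difference was estimated for 205 and 46 genes, and a 4-fold difference for 86 and 10. Without 1 library the count was 294, 405 and 336 (untreated HCC38 1, 2 and 3), 326 and 327 (treated HCC38 1 and 3), 393, 420 and 966 (untreated MDA-MB-231 1, 2 and 3) and 1466, 347 and 311 (treated MDA-MB-231 1, 2 and 3). It was 2218 with a term for the parts of the MDA-MB-231 libraries, which shared 637 with the main result, 2671 with the second part alone, 1254 with no filter, 1315 in DESeq2, 265 on log2(FPKM + 1) and 92 against a 1.5-fold change.

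Between the lines the sets of called genes overlapped. Higher in both were 216 genes against 28 for independent lists (Fisher's exact test, 2-sided p = 1.2e-142), and lower in both 85 against 13.7 (p = 3.05e-45). Higher in HCC38 and lower in MDA-MB-231 were 10 genes (26.3 for independent lists), and the reverse held for 11 (14.6). Of the 216 shared risers 160 rose more in MDA-MB-231 by estimate, with 87 called higher and 4 lower in the difference. Untreated, 127 of them were lower and 57 higher in MDA-MB-231 than in HCC38, and treated, 87 were lower and 87 higher. Their median log2 fold change was 0.87 in HCC38 and 1.43 in MDA-MB-231, and MDA-MB-231 against HCC38 it was -0.65 without and 0.02 with interferon-β.

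Of the 60 antiviral genes 40 responded more in MDA-MB-231 over all genes (43 more and 1 less adjusted over the list alone), with a median difference of 1.24 (camera, adjusted p = 1.31e-39). ISG15 differed by 1.65 ± 0.18 (adjusted p = 0.000104), IFITM1 by 5.62 ± 0.19, HSH2D by 5.80 ± 0.29 and IFI27 by 4.40 ± 0.16. TRIM22 differed by 5.72 ± 0.35, or by 6.37 without untreated MDA-MB-231 replicate 1. IFIT1 did not pass (1.03 ± 0.51, adjusted p = 0.307), but differed by 1.93 (adjusted p = 3.06e-05) without untreated MDA-MB-231 replicate 3. Of the 7 signature genes 5 responded more in MDA-MB-231, also adjusted over the list alone, with a median of 1.65 (camera, adjusted p = 3.01e-11). Among them IFI44 differed by 1.69 ± 0.24.

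MHC class I genes were higher in the difference for 10 of 21 members and lower for 1 (14 and 1 adjusted over the list alone), with a median of 0.44 (camera, adjusted p = 7.46e-07; adjusted p = 0.284 with an estimated correlation). HLA-B differed by 1.22 ± 0.15, TAP1 by 1.4 ± 0.16 and PSMB9 by 2.14 ± 0.17, while HLA-F (1.19 ± 0.14) was not called on FPKM. MHC class II genes differed for 4 of 13 members (6 adjusted over the list alone; median 1.73; camera, adjusted p = 0.000195; adjusted p = 0.274 with an estimated correlation). HLA-DPA1 differed by 2.51 ± 0.50 and CTSS by 1.21 ± 0.20. Interferon signalling genes differed for 3 of 22 members (4 adjusted over the list alone; median 0.13; camera, adjusted p = 0.0145; adjusted p = 0.274 with an estimated correlation). STAT2 differed by 0.81 ± 0.15, and was not called on FPKM. IRF9 differed by 2.55 ± 0.63 (adjusted p = 0.0411), a call lost without any of 9 of the libraries (adjusted p = 0.0726 to 0.118). Chemokines and cytokines differed for 2 of 12 members, also adjusted over the list alone, with a median of 0.43 (camera, adjusted p = 0.0434; adjusted p = 0.274 with an estimated correlation). That call was lost without untreated HCC38 replicate 2 (adjusted p = 0.123) or 3 (0.0567), treated HCC38 replicate 1 (0.0519) or 3 (0.0761) or untreated MDA-MB-231 replicate 2 (0.0740). CXCL16 differed by 1.42 ± 0.28. Nucleic acid sensing genes had 5 of 21 members higher, also adjusted over the list alone (median 0.07; camera, adjusted p = 0.124). Immune ligands were not called (median 0.03, adjusted p = 0.964). IRF3 differed by 0.49 ± 0.18 (adjusted p = 0.162), and by 0.61 (adjusted p = 0.0293) without treated MDA-MB-231 replicate 1.

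Genes of G1/S and DNA replication, with medians of 0.14 in HCC38 and -0.13 in MDA-MB-231, were lower in the difference for 4 of 50 members (13 adjusted over the list alone), with a median of -0.27 (camera, adjusted p = 2.6e-07; adjusted p = 0.627 with an estimated correlation). With the term for the parts 30 were, with a median of -0.38 (camera, adjusted p = 4.5e-17; adjusted p = 0.00335 with an estimated correlation). MCM6 differed by -0.73 ± 0.12 (adjusted p = 0.00386) and CCND1 by -0.69 ± 0.11 (adjusted p = 0.0044). The ATR-CHK1 list had a median of -0.13 (camera, adjusted p = 0.0618) and 0 of 36 genes called in edgeR, with 6 lower at an unadjusted p under 0.05, 3 lower in DESeq2 and 0 in limma-voom. It passed without treated HCC38 replicate 2 (adjusted p = 0.0427) or, of MDA-MB-231, without untreated replicate 1 (0.0107) or 2 (0.00301) or treated replicate 2 (0.00854) or 3 (0.0177). With the term for the parts 11 members were lower (median -0.26; camera, adjusted p = 4.26e-05; adjusted p = 0.201 with an estimated correlation). CHEK1 differed by -0.36 (adjusted p = 0.107) and ATR by -0.31 (adjusted p = 0.325). Homologous recombination and Fanconi genes had a median of -0.14 (camera, adjusted p = 0.0719). They passed without treated HCC38 replicate 2 (0.0392) or, of MDA-MB-231, untreated replicate 1 (0.0213) or 2 (0.00415) or treated replicate 2 (0.00282) or 3 (0.0315), and with the term for the parts (1.1e-05; adjusted p = 0.219 with an estimated correlation).

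Cell death genes went both ways, with 4 of 35 higher and 2 lower (8 and 2 adjusted over the list alone; median 0.01; camera, adjusted p = 0.553). FAS (1.31 ± 0.26) and APOL1 (1.36 ± 0.25) responded more in MDA-MB-231 and PMAIP1 less (-0.90 ± 0.15, adjusted p = 0.00363). Mesenchymal genes also went both ways, with 5 of 31 higher and 3 lower (6 and 4 adjusted over the list alone, median 0.16, camera, adjusted p = 0.482). TGFBI (0.98 ± 0.12) was higher and AXL, which rose in HCC38 and fell in MDA-MB-231, lower (-1.22 ± 0.11). The basal marker ACTA2 differed by 3.14 ± 0.45. MMP13 differed by 6.49 ± 0.44, or by 7.56 without untreated MDA-MB-231 replicate 3, which leaves 1 untreated count. Luminal markers were higher in the difference for 4 of 19 members (8 adjusted over the list alone; median 0.43; camera, adjusted p = 0.00477; adjusted p = 0.284 with an estimated correlation).

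The integrated stress and unfolded protein response list, with medians of -0.08 in HCC38 and -0.24 in MDA-MB-231, had a median difference of -0.25 (camera, adjusted p = 0.0209; adjusted p = 0.778 with an estimated correlation). The call was lost without untreated replicate 1 (0.0805) or treated replicate 2 (0.105) or 3 (0.105) of MDA-MB-231, and with the term for the parts (0.0692). Its 25 members gave 0 calls in edgeR, with 1 higher and 5 lower at an unadjusted p under 0.05, 3 lower in DESeq2 and 0 in limma-voom. Ribosomal protein genes had 3 of 42 lower, also adjusted over the list alone, with a median of -0.02 (camera, adjusted p = 0.594), and passed without treated MDA-MB-231 replicate 1 (0.0429). Fibroblast and endothelial markers (0.91, adjusted p = 0.0711) passed without replicate 1 of untreated HCC38 (0.0216), untreated MDA-MB-231 (0.0465) or treated MDA-MB-231 (0.0358), or treated HCC38 replicate 3 (0.0439). The remaining lists were not called with all 12 libraries and no term for the parts, with medians from -0.37 (APOBEC3, adjusted p = 0.964) to 0.23 (leukocyte markers, adjusted p = 0.885). Of MDA-MB-231, leaving out untreated replicate 2 called other DNA repair (0.0254), untreated replicate 1 (0.0364) or treated replicate 2 (0.0398) called glycolysis and hypoxia, and treated replicate 1 called NF-κB targets (0.0358). With the term camera called G2/M genes (8 lower, adjusted p = 5.0e-05), other DNA repair (10 lower and 1 higher, 0.0203), glycolysis and hypoxia (0.0116), cholesterol synthesis (0.0389) and fibroblast and endothelial markers (0.0374). None of these 5 was called with an estimated correlation, the smallest being adjusted p = 0.212 for other DNA repair.

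**Figure D3:**
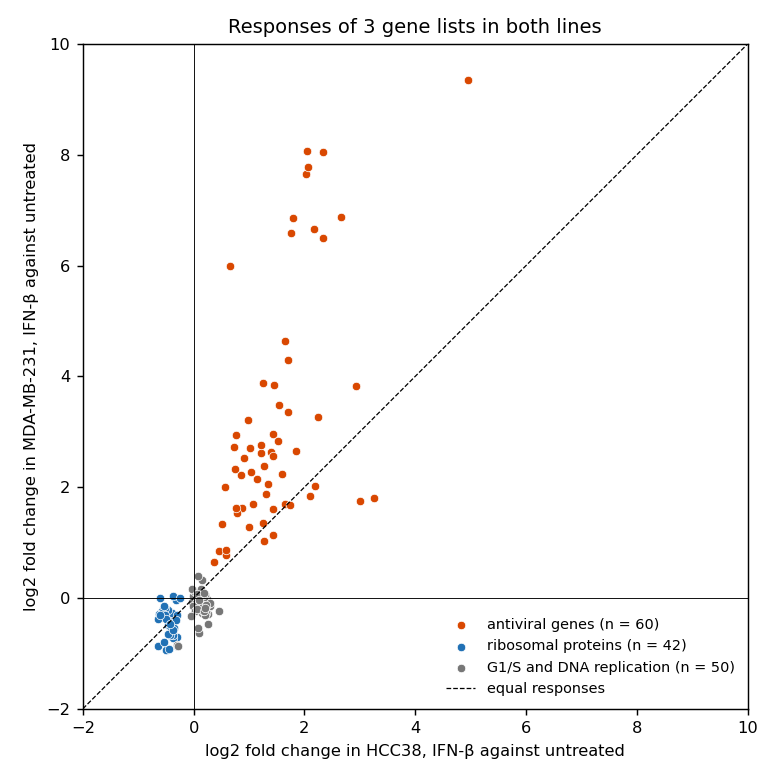
Log2 fold change after interferon-β in HCC38 (horizontal axis) and in MDA-MB-231 (vertical axis) of tested antiviral genes (n = 60), ribosomal protein genes (n = 42) and G1/S genes (n = 50), with 1 point per gene. On the dashed line both responses are equal; the antiviral genes lie mostly above it, with a median difference of 1.24, and the ribosomal protein genes lie to the lower left of zero, with medians of -0.43 and -0.38.

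Untreated, MDA-MB-231 and HCC38 differed in antiviral, antigen presentation, epithelial and histone genes, which were lower in MDA-MB-231, and in glycolysis and ribosomal protein genes, which were higher. None of these calls held (adjusted p = 0.0665 to 0.622 with an estimated correlation), and MHC class I was not called with the term for the parts. OAS1 was at 1.10 ± 0.151 CPM in MDA-MB-231 and 55.1 ± 0.155 CPM in HCC38 (n = 3 each). SLFN11, whose protein blocks stressed replication forks, was at 0.0461 ± 0.0232 CPM against 113 ± 6.19 CPM (-11.08 ± 0.19, adjusted p = 4.44e-15). In edgeR 13673 of 18121 genes differed, 6601 higher and 7072 lower in MDA-MB-231, at least 2-fold for 3636 and 4524 and 4-fold for 1752 and 2932. These differences between lines also hold the difference between their media. A fit with the term for the parts called 14356 genes, of which 13500 were shared in direction.

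Of the 60 antiviral genes 44 were lower and 10 higher in untreated MDA-MB-231, also adjusted over the list alone, with a median of -1.08 (camera, adjusted p = 0.000209; adjusted p = 0.312 with an estimated correlation). MX1 was lower by -6.43 on the log2 scale and ISG15 by -0.57. The signature had 5 of 7 genes lower and 1 higher (median -1.67; camera, adjusted p = 0.0891). Interferon signalling genes had 15 of 22 lower and 6 higher (median -0.54; camera, adjusted p = 0.262). IRF3 was higher at 49.2 ± 0.992 against 37.7 ± 4.47 CPM (0.38, adjusted p = 0.0133), a call lost without untreated HCC38 replicate 3 (adjusted p = 0.0634). IRF7, with 0 counts in HCC38 and 6.35 ± 1.34 CPM in MDA-MB-231, was at least 204-fold higher. STING1 (0.79) and CGAS (0.30, adjusted p = 0.00127) were higher. MHC class I genes had 13 of 21 lower and 3 higher (14 and 3 adjusted over the list alone), with a median of -0.83 (camera, adjusted p = 0.0272; adjusted p = 0.622 with an estimated correlation), a call lost without untreated MDA-MB-231 replicate 3 (0.0549) and with the term for the parts (0.0773). MHC class II genes had 11 of 13 lower, also adjusted over the list alone (median -2.38; camera, adjusted p = 0.0104; adjusted p = 0.437 with an estimated correlation).

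In the ATR-CHK1 pathway 15 of 36 genes were higher and 10 lower in untreated MDA-MB-231 (14 and 10 adjusted over the list alone; median 0.17; camera, adjusted p = 0.453). CHEK1 was at 84.4 ± 7.72 against 37.3 ± 1.53 CPM (1.18 ± 0.08, adjusted p = 6.02e-09). ATR was at 85.3 ± 15.7 against 102 ± 8.82 CPM (-0.25, adjusted p = 0.0583), and was called lower without untreated HCC38 replicate 1 (-0.30, adjusted p = 0.0480) or untreated MDA-MB-231 replicate 3 (-0.41, adjusted p = 0.000815). BRCA1 was higher, at 113 ± 25.8 against 30.6 ± 3.82 CPM. The repair gene MGMT, which removes alkyl groups from guanine, had 14.8 ± 0.900 CPM in HCC38 and 0 counts in MDA-MB-231, at least 507-fold lower. The lists of homologous recombination (median 0.10) and other DNA repair (-0.05) each had an adjusted p of 0.986. In the Schlafen and SAMHD1 list 6 of 11 genes were lower and 4 higher (median -0.68; camera, adjusted p = 0.309). G1/S genes had 26 of 50 higher and 9 lower (median 0.35; camera, adjusted p = 0.0538), and passed without untreated MDA-MB-231 replicate 1 (0.0289) or 2 (0.0173). APOBEC3B, a cytidine deaminase, had 2 counts over the HCC38 libraries and 45.8 ± 3.77 CPM in MDA-MB-231, a ratio of 2289 (95% counting interval 633 to 18902).

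Glycolysis and hypoxia genes were higher in untreated MDA-MB-231 for 21 of 29 members and lower for 3, also adjusted over the list alone (median 0.96; camera, adjusted p = 0.000102; adjusted p = 0.331 with an estimated correlation). Ribosomal protein genes were higher for 32 of 42 and lower for 1, also adjusted over the list alone (median 0.57; camera, adjusted p = 0.000127; adjusted p = 0.583 with an estimated correlation). Histone genes were lower for 15 of 16, also adjusted over the list alone, with a median of -6.03, or -5.50 with genes at 0 counts at their bound (camera, adjusted p = 3.23e-07; adjusted p = 0.0665 with an estimated correlation), such as H1-2 at 19.4 ± 0.937 against 590.3 ± 13 CPM. Luminal markers were lower for 18 of 19, also adjusted over the list alone (median -4.19; camera, adjusted p = 1.28e-06; adjusted p = 0.107 with an estimated correlation). KRT19, a keratin of simple epithelia, was at 0.428 ± 0.112 against 308 ± 18.7 CPM. Leukocyte markers were lower for 9 of 9 tested, also adjusted over the list alone (median -2.85; camera, adjusted p = 0.00834; adjusted p = 0.183 with an estimated correlation). Untested CD68 had 2.22 FPKM in HCC38, 106 in MDA-MB-231. Fibroblast and endothelial markers were lower for 8 of 13 and higher for 2, with a median of -6.37, or -3.47 with genes at 0 counts at their bound (camera, adjusted p = 0.0955). Among the largest differences, NID1, a basement membrane protein, had 0 counts in MDA-MB-231 and 284 ± 7.42 CPM in HCC38, at least 9725-fold lower. CAAP1 was at least 1094-fold higher.

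The remaining lists were not called between the untreated lines without the term for the parts, with adjusted p-values by camera from 0.0766 (chemokines, median -1.15) to 0.99 (cholesterol synthesis, -0.02). Among them were p53 targets (0.14), cell death genes (0.24), mesenchymal genes (-0.43), basal markers (-1.13) and APOBEC3 genes (2.26, or 2.21 with genes at 0 counts at their bound). With the term camera called chemokines (0.0304) and the stress responses (0.0158), but not with an estimated correlation (adjusted p = 0.352 and 0.483).

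With interferon-β, the antiviral genes of the lines came to levels that differed less as a list, while camera again called the epithelial, histone, glycolysis and ribosomal protein lists. None of these held (adjusted p = 0.0633 to 0.873 with an estimated correlation). Of the 60 antiviral genes 31 were higher and 18 lower in treated MDA-MB-231, also adjusted over the list alone, with a median of 0.32 (camera, adjusted p = 0.291). OAS1 was at 301 ± 24.2 against 228 ± 3.04 CPM (0.40 ± 0.08, adjusted p = 0.000216) and ISG15 at 533 ± 55.7 against 253 ± 36.3 CPM (1.07), while MX1 was at 346 ± 20.0 against 889 ± 50.5 CPM (-1.36). In edgeR 13581 of 18121 genes differed, 6653 higher and 6928 lower in MDA-MB-231, at least 2-fold for 3786 and 4231 and 4-fold for 1877 and 2659. The fit with the term, for the first part, called 13635, of which 12597 were shared in direction, and 8996 differed by over 1.5-fold.

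IRF3 was higher in treated MDA-MB-231, at 63.6 ± 12.1 against 34.7 ± 3.67 CPM (0.87, adjusted p = 2.07e-05), and IRF7, with 88.8 ± 9.23 CPM against 0 counts, was at least 2553-fold higher. ATR was lower, at 71.1 ± 5.63 against 105 ± 5.51 CPM (-0.56, adjusted p = 0.000432), and CHEK1 higher, at 75.9 ± 3.21 against 43.0 ± 2.2 CPM (0.82). Histone genes were lower for 15 of 16, with a median of -5.48, or -5.01 with genes at 0 counts at their bound (camera, adjusted p = 2.43e-07; adjusted p = 0.0633 with an estimated correlation). Luminal markers were lower for 18 of 19 and higher for 1 (median -3.30; camera, adjusted p = 9.61e-06; adjusted p = 0.155 with an estimated correlation). Leukocyte markers were lower for 8 of 9 tested (median -4.17; camera, adjusted p = 0.00966; adjusted p = 0.18 with an estimated correlation). Glycolysis and hypoxia genes were higher for 23 of 29 and lower for 3 (median 1.19; camera, adjusted p = 4.79e-05; adjusted p = 0.409 with an estimated correlation). Ribosomal protein genes were higher for 32 of 42 and lower for 1 (median 0.55; camera, adjusted p = 0.000245; adjusted p = 0.873 with an estimated correlation). These 5 lists gave the same counts adjusted over the list alone. The other lists were not called, with adjusted p-values by camera from 0.174 (MHC class II, median -1.35) to 0.964 (cholesterol synthesis, median -0.03).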

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

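Chosen only after the results were seen were the tests of the parts of the MDA-MB-231 libraries and of HCC38 RNA, while the test of shared chance values and the splits were fixed before. The responses to interferon-β differed between the lines for 637 genes by edgeR's interaction test. Each gene below passed that test, and each list passed camera for the difference (MDA-MB-231 minus HCC38, log2). Of the 9 lists only the antiviral genes and the signature were also called with an estimated correlation.

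Higher in this difference were OAS1 (6.02), HSH2D (5.80), TRIM22 (5.72), IFI44L (5.70), IFITM1 (5.62), MX1 (5.07), IFI27 (4.40), IFI44 (1.69), ISG15 (1.65), APOL1 (1.36), SAMHD1 (1.33), IFIH1 (1.32), PLSCR1 (1.31), IRF9 (2.55), STAT2 (0.81) and ADAR (0.71). The same held for the antigen presentation genes HLA-DPA1 (2.51), PSMB9 (2.14), TAP1 (1.4), HLA-B (1.22), CTSS (1.21) and HLA-F (1.19), for MMP13 (6.49), ACTA2 (3.14), LGR4 (1.68), CXCL16 (1.42), ADAMTS16 (1.36), FAS (1.31) and TGFBI (0.98). Lower were NT5E (-3.06), COL13A1 (-2.37), AXL (-1.22), PMAIP1 (-0.90), MCM6 (-0.73) and CCND1 (-0.69). As lists, the median difference was 1.24 for antiviral genes, 1.65 for the signature, 0.13 for interferon signalling, 0.44 for MHC class I, 1.73 for MHC class II, 0.43 for chemokines, 0.43 for luminal markers, -0.27 for G1/S genes and -0.25 for the stress responses.

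The larger rise of the antiviral genes in MDA-MB-231 was weighed against 3 technical explanations. With a term for the parts of its libraries the median difference was 1.22 (spread over the left-out libraries 0.0705), so the parts are not the whole cause. HCC38 RNA in the treated MDA-MB-231 libraries could make up 0.0311% (0.0364% in the highest library), from 44 genes abundant in treated HCC38 and at 3 counts at most in untreated MDA-MB-231, whereas the rise would need a median share of 101%. Chance values of shared untreated libraries do not give it either. From separate libraries, the untreated difference and the difference of responses had a Spearman rho of -0.569 (bootstrap SD 0.121, listed genes not independent). As a response subtracts the untreated level, rho cannot show a lower level sets the rise. This is a hypothesis from the same data: the lower level was not called with an estimated correlation, with medium and line not separable.

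Of the 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05, the real split alone (1) called as many genes in HCC38 (659, highest other 0), between the untreated lines (13673, highest other 0) and between the treated lines (13581, highest other 0). In MDA-MB-231 2 of the 10 splits did: the real one called 2272 genes, and the split that follows the parts called 2462, so these samples hold a structure beside the treatment, and the fit with a term for the parts called 4095. For the difference of responses 5 of 100 drawn relabelings, the real one included, gave as many genes as the real 637, the highest other being 1732, so chance is not excluded for that count. Of the others 3 divided MDA-MB-231 by the parts, and 1 kept its treatment labels and relabelled HCC38.

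Outside the counts used above, 278 genes had a mean FPKM of at least 1 with at most 12 counts over the 12 libraries.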

How the results depend on the processing

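Alternatives with a term for the MDA-MB-231 parts, or with 1 part, were chosen after seeing the data. Over the alternatives, 6889 of 7220 values of genes taken by the naming rule kept their direction and side of the threshold, 214 lost their call, 115 gained one and 2 reversed, and of 2046 list tests 1867 kept both, 78 lost, 96 gained and 5 reversed. The 659 genes of HCC38 became 1131 with no filter, 1136 in DESeq2, 402 and 301 on log2(FPKM + 1) and log2(FPKM + 0.1), 88 against a 1.5-fold change, 1959 in a fit of its 6 libraries, 1913 with the parts' term and 340 to 467 leaving out 1 library. In MDA-MB-231 the 2272 became 1181 and 1190 on FPKM, 1058 on unfiltered FPKM, 275 against a 1.5-fold change, 1035 with 6 libraries, 4095 with the term, 1176 and 3710 in the first and second part, and 1168 to 3263 leaving out 1 library. The 637 differing responses became 1254 with no filter, 1315 in DESeq2, 265, 233 and 260 on FPKM, 92 against a 1.5-fold change, 2218 with the term, 2671 with the second part and 294 to 1466 leaving out 1 library. Between the treated lines 8996 of 13581 genes passed the 1.5-fold test. A test against 1.5-fold asks for more than any change; for the other shifts, also upward ones with a library left out, the cause was not tested. With an estimated correlation, called lists went from 18 to 10 in HCC38, 17 to 8 in MDA-MB-231, 9 to 2 for the difference, and 8 and 5 to 0 between untreated and treated lines, where fry called 23 and 22; the term gave 15 for the difference. IFIT1 between untreated lines ran from -0.35 to 0.86 leaving out 1 library and was -0.36 in the first part. The G2/M list reversed with the term (MDA-MB-231, adjusted p = 0.000155) and without untreated replicate 3 (difference, 0.00268; range 0.00268 to 0.994). Between treated lines fry, which sets no list against other genes, reversed interferon signalling (0.000242), immune ligands (0.00295) and stress responses (0.00668). The title numbers did not pair the libraries: same-number HCC38 pairs correlated at 0.0364, -0.120 and 0.0237, not always the highest. With that replicate block the counts were 633, 2152, 532, 13643 and 13546, in the order HCC38, MDA-MB-231, difference, untreated and treated lines, and 1958 with the numbers of the deposited names in MDA-MB-231. The promoter search was not run. Genes near the floor of 3 counts per group carry wide counting intervals.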

Other observations

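Of the tests below, those of ribosomal protein genes and of the chromosome 9 genes were chosen only after the results were seen. Some genes could be read only from FPKM, since the deposited counts held almost none of them. IFI30, the lysosomal thiol reductase of antigen processing, rose in MDA-MB-231 from 44.2 ± 3.53 to 89.3 ± 14.4 FPKM (SD, n = 3; limma, log2(FPKM + 1) change 0.99 ± 0.11, adjusted p = 0.000279), and in HCC38 it was at 47.8 ± 0.808 and 65.3 ± 3.15 FPKM (adjusted p = 0.0621). USP41, a paralog of the ISG15 protease gene USP18, rose in both lines (1.25 ± 0.16 and 1.18 ± 0.16), with reads that the copies could share. EEF1G, a translation elongation factor with 0 counts, fell in MDA-MB-231 from 1814 ± 320 to 1092 ± 168 FPKM (adjusted p = 0.00857), beside 888 ± 34.3 and 643 ± 15 FPKM in HCC38. CD68, a lysosomal glycoprotein, rose in MDA-MB-231 from 106 ± 15.5 to 174 ± 28.5 FPKM.

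Ribosomal protein genes fell in both lines. With an estimated correlation the list was not called in MDA-MB-231 (adjusted p = 0.116). Nor was it, with a term for the parts, in either line (0.0624 in HCC38 and 0.127 in MDA-MB-231). Over 3 scalings and both lines the median nearest to 0 was -0.296 (spread 0.0886), so scaling is not the whole cause. For 166 other genes matched on transcript length and level, the median in MDA-MB-231 was -0.06 against -0.38, a share of 0.146 (bootstrap SD 0.0462). In HCC38 the share was 0.449 (SD 0.0606, -0.19 against -0.43). Matching on exon length instead, the first choice, gave 0.225 in MDA-MB-231 and -0.00963 in HCC38. Which line had the larger share depended on the matching, so a general fall of short, abundant transcripts stays open as a part in both. A biological cause through interferon-β remains untested.

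In HCC38, 7 neighbouring genes of chromosome 9 between 25676969 and 27573866 (GRCh38), TUSC1, ENSG00000276759, CAAP1, PLAA, IFT74, MOB3B and C9orf72, had 0 counts in all 6 libraries. In a permutation test, 0 of 10000 random orders of the 258 genes with at most 6 counts in HCC38 and a mean of at least 1 CPM in MDA-MB-231 gave a run as long (p = 0.0001, the smallest they can give), and the longest random run was 4. Counting that lost their reads is argued against by the deposited FPKM, which were 0 in HCC38 for each of the 7 genes and 0.247 to 21.7 in MDA-MB-231. A loss of this segment is a candidate explanation, but with 0 counts it cannot be told apart from silencing of its genes, since no DNA was measured. In MDA-MB-231 the longest such run, 8 genes of chromosome 6 between 26195595 and 26234987 with H2BC7 and H4C5 among them, held 1 count (permutation test, p = 0.0001, the smallest possible; longest random run 6).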
